A study of Homo sapiens with 6 samples.

How the data were processed

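RNA was measured in MDA-MB-231 cells, a human breast cancer cell line, after transfection with 1 of 3 small interfering RNAs (siRNAs): siATM against ATM, sip53 against p53, or the control siRNA siNC. Per the labels, each siRNA has 2 samples, total RNA was extracted with a column kit, and biotin-labelled cDNA was hybridised to an Affymetrix Human Gene 2.0 ST array, 1 sample per array. The labels do not say whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

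The deposited table holds 1 value per probe set and array on a log2 scale. The scale was read from the values, which lie between 1.33 and 14.2 with a median near 6 in each array and include no missing value. How the authors corrected background, summarised probes and normalized the arrays, and the annotation build they used, is not given in the sources used here. The sorted values of the 6 arrays differed by 0.0325 on average between the highest and the lowest array, so the deposited log2 values had been brought to nearly the same distribution. Such scaling removes any change in total RNA per cell, and summarised array values compress fold changes of dim probe sets. Scanner files were not used here, so no detection call, scan date or batch could be tested, and the number of arrays limits the precision.

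Probe sets were named through the platform annotation supplied for this work. Of 53617 probe sets, 16098 were paired with 1 gene symbol, 0 with several, and 37519 were unnamed here. All 16098 symbols equalled the current symbol of their gene identifier. They covered 14884 genes, of which 779 had more than 1 probe set. For those the probe set with the highest mean over all arrays was used. The transcripts of the 2 targeted genes are not reported here, so the depth of each knockdown is not analysed here. Gene coordinates are not given because no genome build is named for the table. Probe sets of near-identical genes share sequence, so values of such genes are uncertain.

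Genes were tested where their mean log2 value over the 6 arrays was at or above 5.96, the median of all probe-set means, which kept 10640 genes and left out 4244. Group means were fitted to all 6 arrays in 1 model with limma (version 3.58.1, R 4.3.3), which leaves 3 residual degrees of freedom, and variances were moderated across genes with eBayes, giving 7.29 degrees of freedom in total. The contrasts were siATM against siNC, sip53 against siNC, and siATM against sip53, the last being the test of whether the 2 knockdowns' effects differ. P-values are two-sided. They were adjusted within each contrast with the Benjamini-Hochberg method, and an adjusted p below 0.05 was called a change. Fold changes are differences of mean log2 values and are given with the moderated standard error (SE).

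The gene lists, the design, the rule for named genes and the alternatives were chosen before the data were examined. Of 37 gene lists, 29 had at least 5 tested members, and 5 had no member named in the annotation used. Others were covered in part, with 17 of 37 p53 targets, 9 of 25 NRF2 targets, 13 of 28 hypoxia and glycolysis genes and 19 of 34 DNA damage genes tested. Lists were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which tests a list's own direction and does not compare it with other genes, were alternatives. No list passed camera with an estimated correlation in any of the 3 contrasts. That correlation was 0.21 for the G1/S list and 0.13 for the G2/M list, above the preset 0.01. Estimates from 3 residual degrees of freedom are imprecise, but the preset p-values of both lists may rest on too low a correlation. For the chemokine (−4.6e-05), ribosomal protein (−0.017) and TGF-beta (0.0097) lists the estimate was below the preset 0.01. A higher correlation was therefore not what ended the calls of these 3 lists. The version with an estimated correlation also refers its statistic to the 3 residual degrees of freedom, while the preset version uses a number set by the genes tested. It can therefore lose calls without any correlation. A lost call shows neither that correlation explains a list's shift nor that the preset call holds.

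The genes named followed a rule. CXCL8 was always reported, because the study behind these arrays is known to follow it, so its choice is not independent of the study. The other genes were the 10 highest and 10 lowest fold changes among called genes whose arrays did not overlap between groups, leaving out symbols that start with LOC, LINC, MIR, SNOR, SCARNA, RNU, RNY or RNA5S or that hold -AS or -IT, which does not remove pseudogenes, and up to 4 called members with the largest change from each list that passed the list test or had at least 3 called members. Genes named outside this rule are said to be so where they appear.

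The procedure was tested on simulated arrays with the real genes' means and moderated spreads for siATM against siNC, each gene being drawn independently. Of 10640 simulated genes, 200 were changed, fewer than the 2708 called in the real arrays. Changes of 0.3 on the log2 scale were recovered in 55.2% of 67 genes, and changes of 0.5 and of 1 in 100% of 67 and of 66 genes, with 20 false calls among the unchanged genes. A list of genes shifted by 0.2 passed camera, and 0 of 28 unshifted lists did.

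The alternatives were no filter, a filter at the 70th percentile of probe-set means, quantile normalization on top of the deposited values, centring each array on its median, a variance trend with robust moderation, only the 4 arrays of the 2 groups compared, the replicate number as a block, the mean of all probe sets of a gene, other thresholds, and leaving out each array in turn. Because both knockdowns are compared with the same 2 control arrays, 100 simulated data sets with unchanged groups gave the correlation and covariance that shared controls alone produce.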

Results

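Transcript levels were measured on 6 arrays, 2 for each siRNA, to find which genes change in MDA-MB-231 cells when ATM or p53 is targeted and whether the 2 siRNAs change the same genes. ATM is the kinase that signals DNA double-strand breaks, and p53 is a transcription factor that acts downstream of it. MDA-MB-231 is a triple-negative breast cancer line that carries a mutant p53. The median log2 value of an array lay between 5.95 and 5.98. Over the 10640 genes tested, the SD of the difference between 2 arrays of 1 group was 0.124 for siNC, 0.148 for siATM and 0.115 for sip53 on the log2 scale, and between arrays of different groups it ranged from 0.205 to 0.291. The first principal component held 56.7% of the variance and set the 2 siATM arrays apart from the other 4. The second held 25.1% and set the siNC arrays apart from the sip53 arrays.

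After siATM, 27 of 28 G2/M genes, 21 of 26 G1/S and replication genes, 12 of 24 interferon-stimulated genes and 9 of 18 chemokine and cytokine genes were lower than in control cells, and 8 of 14 TGF-beta and BMP response genes were higher. These 5 lists passed camera with a preset correlation, and none passed with an estimated correlation (adjusted p = 0.247 to 0.325). The latter test has only 3 degrees of freedom, so its failure does not show that correlation explains these shifts. CXCL8, the neutrophil chemokine interleukin 8, was the gene with the largest fall. Its log2 value was 8.05 ± 0.09 (SD, n = 2) with siNC and 6.09 ± 0.05 (SD, n = 2) with siATM, a 3.89-fold difference (log2 fold change −1.96, SE 0.07, adjusted p = 4.79e-05). CALCR, the calcitonin receptor, had the largest rise, from 6.48 ± 0.05 to 8.10 ± 0.05 (SD, n = 2 each), or 3.09-fold.

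In all, 2708 of the 10640 genes changed after siATM, 1325 of them higher and 1383 lower (limma, adjusted p below 0.05). Most changes were small, with a median size of 0.35 on the log2 scale, and 134 genes were at least 1.5-fold higher and 211 at least 1.5-fold lower. Below CXCL8, the genes with the largest falls were MBOAT1, a membrane-bound acyltransferase, at 3.18-fold, CHRDL1, a secreted BMP antagonist, at 3.14-fold, PRRG4 at 3.02-fold, the interferon-inducible GTPase GBP4 at 2.74-fold and QNG1 with a log2 fold change of −1.39 (SE 0.09). ANXA8 and ANXA8L1 fell 2.59-fold and 2.51-fold, but these are near-identical genes whose probe sets cannot be counted as separate. PDCD1LG2, which encodes the immune checkpoint ligand PD-L2, fell 2.45-fold, and the pseudogene HNRNPA1P33 had a log2 fold change of −1.20 (SE 0.21). Below CALCR, the genes with the largest rises were DSEL at 2.67-fold, KITLG, the ligand of the KIT receptor, at 2.60-fold, LRRC15 (log2 fold change 1.32, SE 0.06), the peptidase DPP4 at 2.49-fold, TSPAN8 (1.30, SE 0.09), OLFML3 (1.29, SE 0.08), the lipopolysaccharide co-receptor CD14 at 2.28-fold, SESN3 at 2.27-fold and CREB3L3 (1.16, SE 0.10). Among the 850 tested genes with the non-coding, antisense or uncharacterised symbols left out of the naming, 83 were higher and 57 lower. Without siNC replicate 1 the number of changed genes was 1437, and without siNC replicate 2 it was 1489. The 19 genes with the largest changes beside CXCL8 remained called when any 1 array was left out, as did 70 of all 113 genes named for this comparison.

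The list of G2/M and mitosis genes fell almost as a whole after siATM. Of 28 members tested, 27 were lower and 0 higher, also when adjusted over the list alone, with a median log2 fold change of −0.53 (camera adjusted p = 6.18e-18; adjusted p = 0.247 with an estimated correlation). The largest falls were in NEK2, a centrosome kinase (2.15-fold), PTTG1, the securin (2.13-fold), the phosphatase gene CDC25C (log2 fold change −0.76, SE 0.06) and PRC1 (−0.72, SE 0.06). Of 26 genes of the G1/S transition and DNA replication, 21 were lower and 0 higher (22 lower adjusted over the list alone), with a median of −0.48 (camera adjusted p = 3.14e-13; adjusted p = 0.247 with an estimated correlation). MCM3, a subunit of the replicative helicase, fell 2.12-fold. MCM10, the thymidylate synthase gene TYMS and GINS2 had log2 fold changes of −0.77, −0.76 and −0.75. Of 19 DNA damage signalling and repair genes, 8 were lower and 1, RAD52, was higher (the same counts adjusted over the list alone). The list's median was −0.11, with camera adjusted p = 0.00436 and adjusted p = 0.283 with an estimated correlation. The members with the largest falls were RAD54L (−0.76), NBN (−0.66), which encodes a subunit of the complex that recruits ATM to breaks, EXO1 (−0.58) and CHEK1 (−0.58).

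Of 24 interferon-stimulated genes, 12 were lower after siATM and 1, BST2, was higher (13 and 1 adjusted over the list alone). RAD52, BST2 and, below, CSF1 were chosen for naming after their values were seen. The list's median log2 fold change was −0.30 (camera adjusted p = 5.28e-05; adjusted p = 0.325 with an estimated correlation). DDX60 had a log2 fold change of −0.72, SAMD9L of −0.69, HERC6 of −0.66 and HERC5 of −0.58. Of 18 chemokine and cytokine genes, 9 were lower and 1, CSF1, was higher (11 and 2 adjusted over the list alone), with a median of −0.22 (camera adjusted p = 0.00741; adjusted p = 0.247 with an estimated correlation). After CXCL8, the largest falls in this list were in CCL2, the monocyte chemoattractant (1.93-fold), CXCL11 (−0.63) and IL11 (−0.58). With genes filtered at the 70th percentile of brightness CXCL8, CCL2 and other members were too dim to be tested, and what was left of the chemokine list did not pass (adjusted p = 0.391).

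The list of TGF-beta and BMP response genes was higher after siATM, with 8 of 14 members higher and 0 lower (9 and 0 adjusted over the list alone), a median of 0.25, camera adjusted p = 0.000834, and adjusted p = 0.247 with an estimated correlation. The largest rises were in 3 inhibitors of the pathway, the pseudoreceptor gene BAMBI (2.10-fold) and the inhibitory SMAD genes SMAD6 (log2 fold change 0.88) and SMAD7 (0.62), and in JUNB (0.45). Immediate-early genes moved both ways, with 9 of 26 higher, among them DUSP1 (0.62), SPRY2 (0.58) and IER5 (0.53), and 4 lower, among them ETV4 (−0.86), or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0405, and adjusted p = 0.283 with an estimated correlation). Of 24 ribosomal protein genes, 4 were higher, led by RPS19 (0.25), and 0 lower (0 and 0 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.00741; adjusted p = 0.247 with an estimated correlation). Of 15 genes of respiratory complexes III to V, 3 were higher (COX6B1, UQCRB and COX5B) and 0 lower (3 and 0 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.0292; adjusted p = 0.543 with an estimated correlation). RPL11, RPL38 and RPS24 lost their call whichever of the 6 arrays was left out (adjusted p up to 0.230, 0.226 and 0.134), and RPS19 lost it without either siNC array (up to 0.0749), so the count of 4 rests on all arrays together. With the filter at the 70th percentile the immediate-early list was at adjusted p = 0.127 and the respiratory list at adjusted p = 0.0949, and neither passed. The immediate-early list also did not pass after quantile normalization (adjusted p = 0.0530) or with the mean of all probe sets of a gene (adjusted p = 0.0777). Both lists lost their call without siNC replicate 2 (adjusted p = 0.0878 and 0.113), the immediate-early list also without siATM replicate 2 (adjusted p = 0.0916) and the respiratory list also without siATM replicate 1 (adjusted p = 0.0927). COX5B lost its call whichever of the 6 arrays was left out (adjusted p up to 0.142), COX6B1 without any 1 of the arrays except siATM replicate 2 (up to 0.128), and UQCRB without siATM replicate 1 or either siNC array (up to 0.113).

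After sip53, 9 of 18 chemokine and cytokine genes were lower than in control cells, and of 17 sterol synthesis genes 6 were higher and 1 lower. Both lists passed camera with a preset correlation and neither passed with an estimated correlation (adjusted p = 0.294 and 0.295). CXCL8 again had the largest fall, from 8.05 ± 0.09 to 5.61 ± 0.10 (SD, n = 2 each), a 5.41-fold difference (log2 fold change −2.44, SE 0.07, adjusted p = 3.98e-05). The sip53 mean lay below 5.96, the median of all probe sets, which was the limit set on a gene's mean over the 6 arrays. CALCR again had the largest rise, to 8.17 ± 0.03 (SD, n = 2), or 3.24-fold (log2 fold change 1.69, SE 0.06, adjusted p = 5.27e-05).

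**Figure D1:**
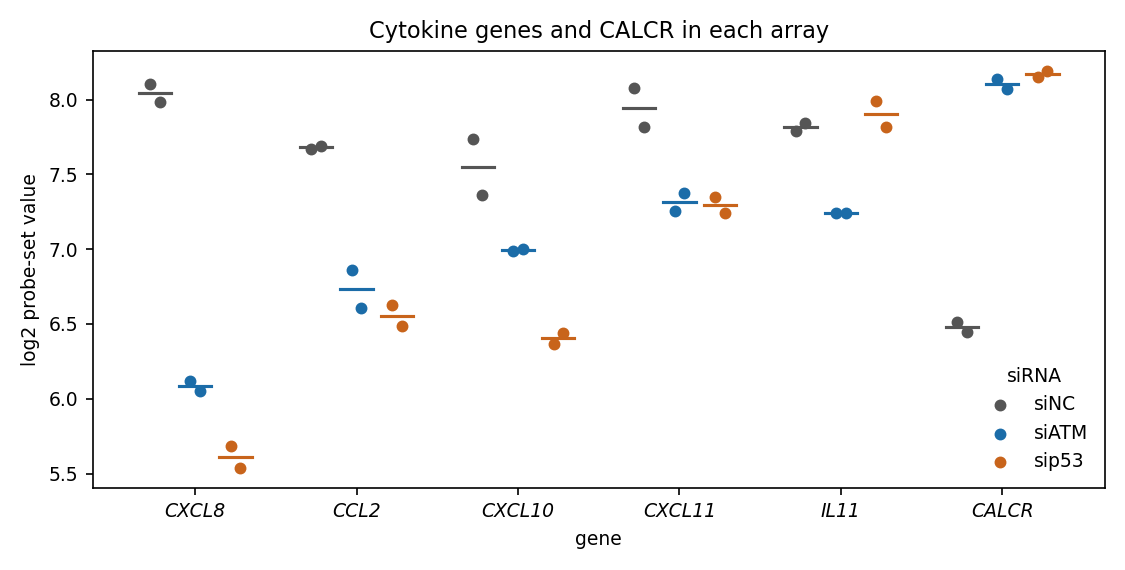
Log2 probe-set values (y axis) of 5 cytokine genes and CALCR (x axis) in each of the 6 arrays; points are arrays and short lines are group means. The siNC points of CXCL8 lie at 8.11 and 7.98, above both siATM points at 6.12 and 6.05 and both sip53 points at 5.68 and 5.54, and CALCR is higher with both siRNAs.

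Of the 10640 genes, 1126 changed after sip53, 582 higher and 544 lower (limma, adjusted p below 0.05). Without the filter on dim genes the count was 481, with 215 higher and 266 lower, and with a variance trend and robust moderation it was 1742. When each array was centred on its median over the tested genes the split was 410 higher and 668 lower, so the balance of directions depends on the scaling. At least 1.5-fold, 60 were higher and 85 lower. Below CXCL8, the genes with the largest falls were ADGRG1, an adhesion G protein-coupled receptor (2.91-fold), CHI3L2 (log2 fold change −1.16, SE 0.12), CXCL10 (2.21-fold), CCL2 (2.18-fold), KYNU, the kynureninase of tryptophan breakdown (2.18-fold), LPGAT1 (−1.07, SE 0.06), SLFN5 (−1.03, SE 0.09), the intermediate filament gene NES (−0.96, SE 0.07) and STC1 (−0.95, SE 0.06). Below CALCR, the genes with the largest rises were CDK15 (0.99, SE 0.08), EVI2A (0.95, SE 0.08), the imprinted gene PEG10 (0.94, SE 0.07), GPR137C (1.91-fold), ASIC1 (0.93, SE 0.10), BTBD8 (0.92, SE 0.08), ZNF138 (0.92, SE 0.06), the ceramidase gene ACER2 (0.92, SE 0.11) and NANOS1 (0.90, SE 0.11). Among the 850 genes with the non-coding, antisense or uncharacterised symbols left out of the naming, 30 were higher and 21 lower. The number of changed genes was 311 without siNC replicate 1, 329 without siNC replicate 2, 289 without sip53 replicate 1 and 272 without sip53 replicate 2. The 19 genes with the largest changes beside CXCL8 remained called when any 1 array was left out, as did 31 of all 71 genes named for this comparison.

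Of the 18 chemokine and cytokine genes, 9 were lower after sip53 and 0 higher (11 and 0 adjusted over the list alone), with a median log2 fold change of −0.31 (camera adjusted p = 2.27e-06; adjusted p = 0.294 with an estimated correlation). Beside CXCL8, CXCL10 and CCL2, the largest fall was in CXCL11 (−0.65), which lost its call in 1 of the 6 fits with 1 array left out. Of 13 NF-kB target genes, 4 were lower and 0 higher (6 and 1 adjusted over the list alone), with a median of −0.12 (camera adjusted p = 0.00438; adjusted p = 0.739 with an estimated correlation). These 4 were ICAM1, a leukocyte adhesion molecule (1.76-fold), the NF-kB subunit genes NFKB2 (−0.43) and NFKB1 (−0.30), and TRAF1 (−0.31). ICAM1 alone kept its call whichever array was left out, while NFKB1 and TRAF1 lost theirs without any 1 of the siNC and sip53 arrays (adjusted p up to 0.151 and 0.138) and NFKB2 without siNC replicate 1 or either sip53 array (up to 0.0726). Of 17 genes of sterol synthesis and its control, 6 were higher and 1 lower (12 and 2 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.000412; adjusted p = 0.295 with an estimated correlation). HMGCS1, the synthase of hydroxymethylglutaryl-CoA, rose 1.61-fold from 9.14 ± 0.02 to 9.83 ± 0.03 (SD, n = 2 each), SQLE, the squalene epoxidase, had a log2 fold change of 0.47, and ACAT2 of 0.46. INSIG1, which encodes an inhibitor of sterol-regulated transcription, fell (−0.46). ACAT2 lost its call in 2 of the 6 fits with 1 array left out, while HMGCS1, SQLE and INSIG1 kept theirs in each. The G2/M list passed with 3 of 28 members lower, KIF11, CENPA and CDC25B, and 0 higher (the same counts adjusted over the list alone), but its median was −0.07 (camera adjusted p = 0.0339; adjusted p = 0.739 with an estimated correlation), and it did not pass without siNC replicate 2 (adjusted p = 0.112) or without sip53 replicate 2 (adjusted p = 0.107). KIF11, CENPA and CDC25B each lost their call without any 1 of the siNC and sip53 arrays (adjusted p up to 0.173, 0.0817 and 0.148).

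The list of known p53 target genes did not pass after sip53. Of its 37 members, 19 were named in the annotation and 17 were tested, so the result covers only part of the list. Of 17 tested, 2 were higher and 2 lower (2 and 4 adjusted over the list alone), with a median of 0.10, a mean of 0.0009 and camera adjusted p = 0.972. GDF15 fell 1.61-fold (log2 fold change −0.69, SE 0.07) and CCNG1 fell (−0.31), while SESN1 (0.42) and PLK2 (0.27) rose. After siATM, 3 of the 17 were higher and 0 lower (2 and 0 adjusted over the list alone), namely the BH3-only gene BBC3 (0.46), PLK2 (0.39) and GDF15 (0.22). The median was −0.05 and the mean 0.03, opposite in sign, with camera adjusted p = 0.773. GDF15 after siATM and PLK2 after sip53 lost their call whichever of the 6 arrays was left out, with adjusted p up to 0.229 and 0.196. After sip53, CCNG1 lost it without any 1 of the siNC and sip53 arrays, with adjusted p up to 0.202, and SESN1 lost it without siNC replicate 2 or either sip53 array, with adjusted p up to 0.130.

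None of the 3 lists of markers of other cell types passed against siNC. Of 7 haematopoietic markers, 2 were higher after siATM, CD14 and LYZ (0.38), and 0 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.280), and after sip53 0 were higher and 1, CD14, was lower (the same counts adjusted over the list alone; camera adjusted p = 0.448). Of 7 endothelial and fibroblast markers, LUM (0.68) and RGS5 (0.25) were higher and PECAM1 (−0.47) was lower after siATM (the same counts adjusted over the list alone; camera adjusted p = 0.740), and LUM (0.49) was higher after sip53 (the same count adjusted over the list alone; camera adjusted p = 0.634). Of 12 luminal epithelial markers, 4 were higher and 1 lower after siATM (6 and 2 adjusted over the list alone; camera adjusted p = 0.290), with AGR2 at 2.21-fold, and GATA3 (0.65), AGR2 (0.32) and KRT7 (0.28) were higher after sip53 (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.634). RGS5 after siATM lost its call without siATM replicate 1 or either siNC array (adjusted p up to 0.135), and AGR2 and KRT7 after sip53 lost theirs without any 1 of the siNC and sip53 arrays (up to 0.173 and 0.127). PECAM1 after siATM lost its call in 1 of the 6 fits with 1 array left out. LYZ, and CD14 and LUM after sip53, were chosen for naming after their values were seen.

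The direct comparison of siATM with sip53 tests whether the 2 knockdowns differ. Lower with siATM than with sip53 were 22 of 26 G1/S and replication genes, 22 of 28 G2/M genes, 15 of 24 interferon-stimulated genes and 9 of 17 sterol genes. These lists passed camera with a preset correlation, and each had adjusted p = 0.258 with an estimated correlation. MBOAT1 differed most and was 4.38-fold lower with siATM (log2 difference −2.13, SE 0.07, adjusted p = 4.74e-05). CD14 was 3.92-fold higher with siATM, at 9.53 ± 0.05 against 7.56 ± 0.22 (SD, n = 2 each). CXCL8 was 1.39-fold higher with siATM than with sip53 (log2 difference 0.48, SE 0.07, adjusted p = 0.00329), and its fall from siNC was the smaller one after siATM. In all, 3219 genes differed, 1487 higher and 1732 lower with siATM (limma, adjusted p below 0.05). When each array was centred on its median over the tested genes 1669 were higher and 1558 lower, so which direction held more genes depends on the scaling. After MBOAT1, the lowest with siATM were PRRG4 (3.08-fold), GPR137C (2.94-fold), GBP4 (2.65-fold), QNG1 (−1.30), PUDP (−1.29), POLR3G (−1.26), EIF5A2 (−1.24), ZNF367 (−1.23) and APMAP (−1.21). After CD14, the highest were LRRC15 (2.63-fold), SELPLG, the ligand of P-selectin (2.54-fold), SESN3 (2.47-fold), PLLP (1.28), DSEL (1.28), HSD17B3 (1.18), SLFN5 (1.16), CD22 (1.15) and CPA4 (1.13). Without sip53 replicate 1 the number of genes that differed was 1842, and without sip53 replicate 2 it was 1884. The 20 genes with the largest differences remained called when any 1 array was left out, as did 92 of all 120 genes named for this comparison.

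Of 26 G1/S and replication genes, 22 were lower with siATM than with sip53 and 0 higher (22 and 0 adjusted over the list alone), led by GINS1 (−1.16), MCM3 (−1.13), MCM10 (−1.07) and the cyclin gene CCNE2 (−0.87), with camera adjusted p = 5.38e-12 and adjusted p = 0.258 with an estimated correlation. Of 28 G2/M genes, 22 were lower, among them PTTG1 (−0.85) and FOXM1 (−0.71), and 0 higher (26 and 1 adjusted over the list alone; camera adjusted p = 5.38e-12; adjusted p = 0.258 with an estimated correlation). Of 24 interferon-stimulated genes, 15 were lower and 1, BST2, was higher (15 and 1 adjusted over the list alone), led by SAMD9L (−0.91), HERC6 (−0.85) and HERC5 (−0.76), with camera adjusted p = 1.07e-05 and adjusted p = 0.258 with an estimated correlation. Of 17 sterol genes, 9 were lower and 1, INSIG1, was higher (10 and 2 adjusted over the list alone), led by HMGCS1 (−0.68), ACAT2 (−0.57) and IDI1 (−0.55), with camera adjusted p = 0.00682 and adjusted p = 0.258 with an estimated correlation. Of 19 DNA damage genes, 8 were lower, led by USP1 (−0.77) and EXO1 (−0.74), and 1, RAD52, was higher (the same adjusted over the list alone). The median of this list was −0.09. Its camera adjusted p was 0.0197, with adjusted p = 0.258 with an estimated correlation and 0.0549 without siATM replicate 2. BST2, INSIG1, RAD52 and the lower members SKIL, TGIF1 and OCLN of the lists that follow were chosen for naming after their values were seen.

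Higher with siATM than with sip53 were 7 of 14 TGF-beta response genes with SKIL and TGIF1 lower (JUNB 0.73, LTBP1 0.71, BAMBI 0.66; camera adjusted p = 0.0304), 5 of 9 antioxidant genes controlled by NRF2 with 0 lower (TALDO1 0.41, TXNRD1 0.38; camera adjusted p = 0.0296), 4 of 18 epithelial junction genes with OCLN lower (CLDN7 1.12, TJP3 0.75, PKP2 0.56; camera adjusted p = 0.0276), 12 of 26 immediate-early genes with 5 lower (DUSP1 0.85, ETV4 −0.76; camera adjusted p = 0.0283) and 4 of 24 ribosomal protein genes with 0 lower (RPL38 0.34; camera adjusted p = 0.0113). Adjusted over the list alone, these counts were 7 and 2, 7 and 1, 4 and 1, 12 and 5, and 1 and 0. Of the 4 ribosomal protein genes only RPL38 kept its call whichever array was left out. RPL22 lost its call in 5 of the 6 fits with 1 array left out, and RPS19 and RPS23 in 3 of 6, those without either sip53 array among them. Of the NRF2 genes, OSGIN1 and TXN each lost their call in 3 of the 6 fits, those without either sip53 array among them. Each of these lists had adjusted p = 0.258 with an estimated correlation. Without siATM replicate 2, 5 lists passed in place of 10, and the TGF-beta, NRF2, epithelial junction and immediate-early lists were each at adjusted p = 0.0549. With the filter at the 70th percentile these 4 lists did not pass either, with adjusted p of 0.0886, 0.103, 0.0939 and 0.0886, and the immediate-early list was at adjusted p = 0.0508 with the mean of all probe sets of a gene. The chemokine list did not pass in this comparison, with 6 of 18 members higher and 1 lower with siATM (6 and 1 adjusted over the list alone; camera adjusted p = 0.113). CXCL10 (0.59) was among the higher members, and IL11 (−0.66) was the lower one.

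**Figure D2:**
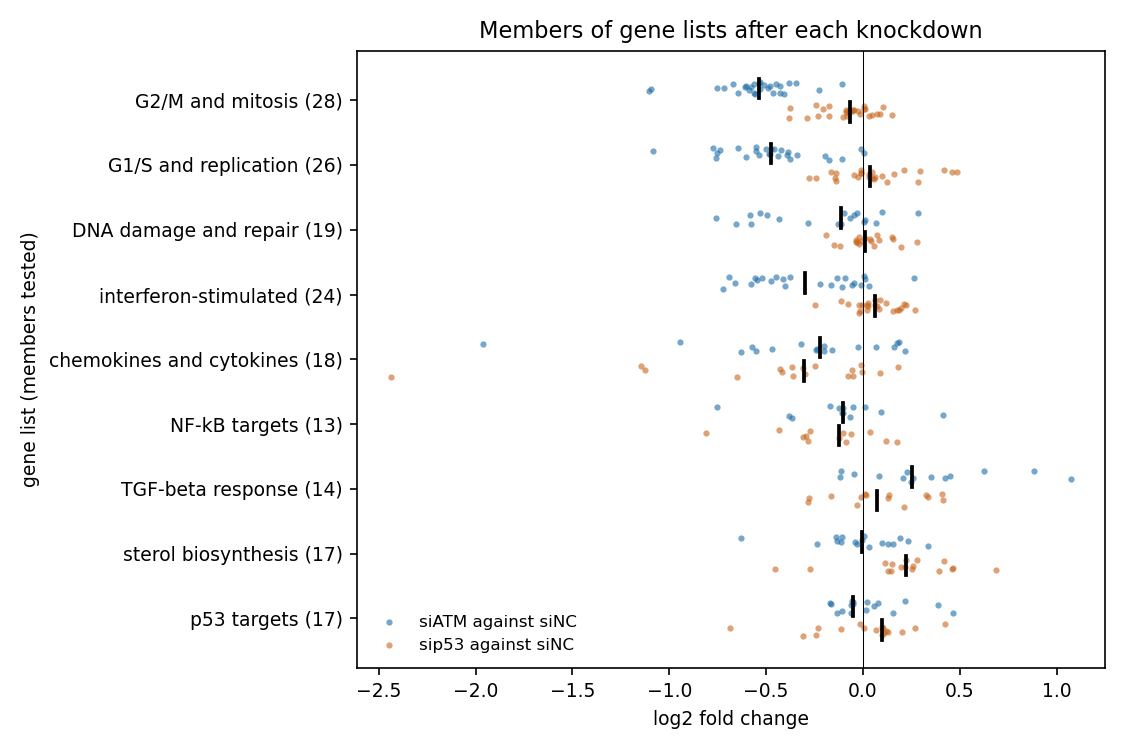
Log2 fold changes against siNC (x axis) of the tested members of 9 gene lists (y axis, with the number tested), in blue after siATM and in orange after sip53; points are genes and black ticks are medians. The G2/M and G1/S medians lie at −0.53 and −0.48 after siATM and at −0.07 and 0.04 after sip53, while the sterol median lies at −0.01 after siATM and 0.22 after sip53.

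CXCL8 and CALCR were among the 536 genes called against siNC after both siRNAs, while 2172 genes were called after siATM and not sip53 and 590 after sip53 and not siATM. Of the 536, 201 were higher after both, among them CALCR, and 196 were lower after both, among them CXCL8 and CCL2. The other 139, among them MBOAT1 and CD14, went in opposite directions, 61 of them higher after siATM and 78 higher after sip53. Independent lists of these sizes would share 72.5 higher and 70.7 lower genes and 143 genes in opposite directions. In 100 simulations of unchanged groups with shared controls 0 genes were called in both comparisons, which gives no overlap to compare with because so few genes are called without effects. Across genes, which are not independent replicates, the fold changes correlated at Pearson r = 0.26 and Spearman rho = 0.23, against 0.50 and 0.46 in the simulations. The simulated groups had no effects, and effects that differ between the siRNAs lower the correlation. The lower observed values therefore do not show less similarity than unchanged groups would have. The covariance of the fold changes was 0.0122, against a simulated 0.0042, a difference of 0.00798. The 2 control arrays could not be split into groups of 2, and part of the overlap above independent lists may come from the shared controls. The number called in the same direction, 397, was 119 without siNC replicate 1, 133 without siNC replicate 2, 132 without sip53 replicate 1 and 130 without sip53 replicate 2. Among the 397, the 2 knockdowns themselves differed in 115.

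**Figure D3:**
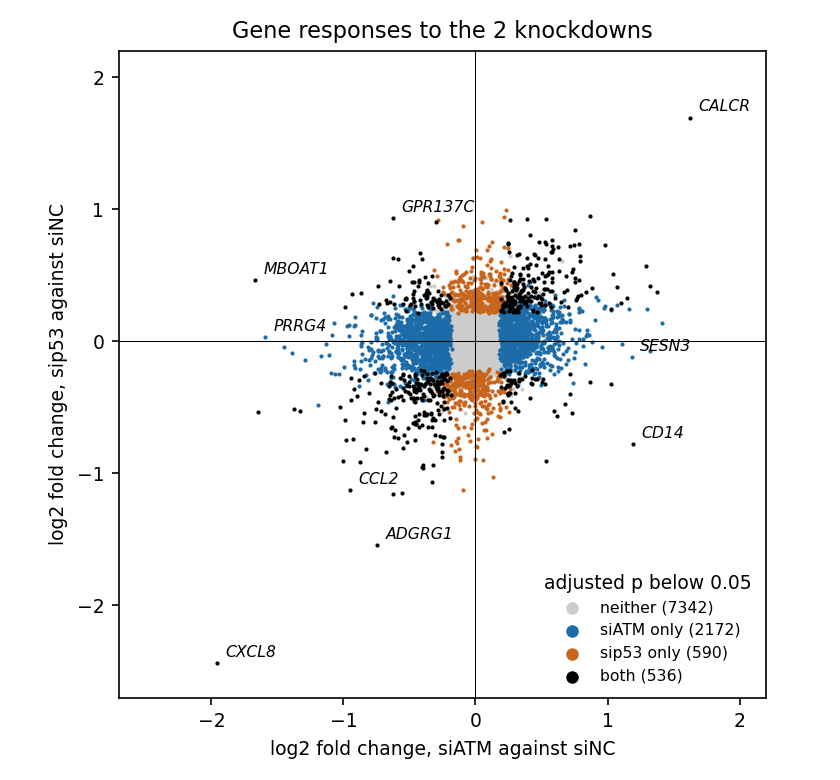
Log2 fold change of each of the 10640 tested genes after siATM (x axis) and after sip53 (y axis), both against siNC; colour gives the comparison in which the adjusted p was below 0.05. CXCL8 lies alone at the lower left (−1.96 and −2.44), CALCR at the upper right (1.63 and 1.69), and MBOAT1 and CD14 lie in the quadrants of opposite change.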

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

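The tests on array scaling, on an interferon reaction, on an unusual control array and on the control siRNA were chosen after the results were seen, and the test on signal brightness was written down before.

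In 10 gene lists the effect of siATM and the effect of sip53 against the same control differed in the direct comparison by camera with a preset correlation, while none of them passed with an estimated correlation (adjusted p = 0.258 for each). The camera adjusted p of the difference was 5.38e-12 for the G1/S list and for the G2/M list, 1.07e-05 for the interferon-stimulated list, 0.00682 for sterol synthesis, 0.0113 for ribosomal proteins, 0.0197 for DNA damage and repair, 0.0276 for epithelial junctions, 0.0283 for immediate-early genes, 0.0296 for NRF2 targets and 0.0304 for the TGF-beta response. Another 139 genes were called in opposite directions by the 2 knockdowns, and their difference passed too, which follows from the sizes of the 2 opposite changes. Probe sets without a gene name here were outside the comparisons above, and 15378 of them were at least as bright as the filter. Of these, 426 were higher and 409 lower after siATM than with siNC, and 16 were higher and 41 lower after sip53 (limma, adjusted p below 0.05 within these probe sets).

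The first pattern weighed is the fall of the G2/M and G1/S lists after siATM, with medians of −0.53 and −0.48. An effect of brightness is argued against, since the lowest median among 10000 random lists as bright as the G2/M list was −0.16. Array scaling or normalization that moves equally bright genes alike is argued against by the same comparison for both lists, since the lowest median among 10000 random lists as bright as the G1/S list was −0.17. The fall is relative to the other genes, because the arrays had been brought to nearly the same distribution. An interferon reaction to the siRNA, which can slow growth, would raise interferon-stimulated genes, whose median was −0.30 with 12 members lower and 1 higher. A fall that follows from knockdown of ATM, other transcripts hit by the siATM siRNA and a difference in cell density at harvest all stay open and were not tested, since siRNA sequences and cell counts were not used here.

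The second pattern is the fall of CXCL8 and the chemokine list with both siRNAs. A single unusual control array is argued against, since without either siNC array CXCL8 still fell by at least 1.90 on the log2 scale in both comparisons and stayed called. Both falls rest on the same control siRNA, which could itself have raised these genes. Of the 6 list members called lower after both siRNAs, CXCL8 and CXCL10 differed between siATM and sip53 (adjusted p = 0.00329 and 0.00788) and the other 4 did not pass, but the list as a whole did not pass between siATM and sip53 (camera adjusted p = 0.113), and CXCL8 is dim after sip53. A rise by the control siRNA therefore cannot be told apart from a fall after both knockdowns, because these arrays hold no untreated cells and no other control siRNA. The same limit holds for the rise of CALCR, which the control siRNA could have lowered. It also holds for the other genes among the 397 called in the same direction after both siRNAs.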

How the results depend on the processing

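All alternatives below were planned. The number of changed genes stayed within 1.5 times the reported one except as follows. Without a filter on dim genes, sip53 against siNC had 481 genes and the overlap in the same direction 180, with 14884 genes tested in place of 10640. With a variance trend and robust moderation sip53 against siNC had 1742 genes. Requiring at least 1.5-fold as well as the adjusted p gave 345, 145 and 504 genes for siATM against siNC, sip53 against siNC and siATM against sip53. An unadjusted p below 0.05 with 1.5-fold gave 347, 147 and 505, and an adjusted p below 0.1 gave 1782 genes for sip53 against siNC. Leaving out each array in turn gave 1437 to 2226 genes for siATM against siNC, 272 to 1242 for sip53 against siNC, 1842 to 2852 for siATM against sip53, and 119 to 379 genes shared in the same direction. The lowest counts come where a group is left with 1 array, which is assumed to vary like the others. CXCL8 stayed called in all comparisons, with log2 fold changes of −2.02 to −1.90, −2.51 to −2.36 and 0.40 to 0.55. The number of lists past camera was 7 to 9, 3 to 4 and 5 to 10 in these fits. Filtering at the 70th percentile left 6 lists in siATM against sip53, and CXCL8 was too dim to be tested there. An estimated correlation left 0 lists in each comparison (lowest adjusted p 0.247, 0.294 and 0.258), and fry gave 18, 8 and 17. In the simulated data a shifted list did pass with an estimated correlation (camera adjusted p = 0.0412, against 2.6e-24 with the preset one). Its genes were simulated without correlation, so the higher p arose without any simulated correlation, in a test with 3 degrees of freedom. For the same reason the pass does not show that a real list with such a shift would pass. Of 4219 values of named genes under 14 settings, 3711 kept direction and call, 507 lost the call and 1 reversed, BMF after siATM, at −0.024 (adjusted p = 0.790) with the mean of its probe sets. Of 368 values of the 23 list calls under 16 settings, 323 kept direction and call and 45 lost the call, 23 of them with an estimated correlation and 7 with the filter at the 70th percentile. Samples with the same replicate number were not taken as pairs. Their deviations from the group means correlated at 0.04, 0.03 and 0.12. The third principal component, with 8.07% of the variance, had 1 sign in the replicate 1 arrays and the other in the replicate 2 arrays. It mainly set the 2 siATM arrays apart (−7.59 and 7.34), with smaller values for siNC (−1.04 and 0.66) and sip53 (−1.34 and 1.99). A replicate block gave 2696, 1001 and 3218 genes and changed no list's call, while 9 named genes lost theirs. The cause of these shifts was not tested. Signal over background could not be judged, so values near the filter, such as CXCL8 after sip53, are the least certain.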

Other observations

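The FOXO list below was chosen after the rise of SESN3 and DEPP1 had been seen, and 5 of its members (TXNIP, KLF6, BCL2L11, GABARAPL1 and ERBB3) also stood in lists tested earlier, while its own test was written down before it was run.

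Of the 139 genes that went in opposite directions with the 2 siRNAs, CD14 was 2.28-fold higher after siATM and 1.72-fold lower after sip53, the claudin gene CLDN7 had log2 fold changes of 0.59 and −0.53, SELPLG of 1.03 and −0.32, and HSD17B3 of 0.87 and −0.31. In the other direction, MBOAT1 had log2 fold changes of −1.67 after siATM and 0.46 after sip53, GPR137C of −0.62 and 0.93, and POLR3G of −0.63 and 0.63. APAF1, the scaffold of the apoptosome, fell 2.05-fold after siATM, and BMF, a BH3-only gene, rose after sip53 (log2 fold change 0.74). Of 17 ATF4 and unfolded-protein targets, 2 were higher and 4 lower after siATM (the same counts adjusted over the list alone), among the lower PSAT1 (−0.52) and ASNS (−0.55), and the list did not pass (camera adjusted p = 0.694). The hypoxia-regulated gene ADM rose after sip53 (0.76), and the carbonic anhydrase gene CA12 fell (−0.57), while the hypoxia and glycolysis list did not pass (camera adjusted p = 0.783). Of 9 CDK, D-type cyclin and retinoblastoma family genes, 4 were lower after siATM, namely CDK6 (−0.68), RBL1 (−0.51), CDK2 (−0.44) and CCND1 (−0.34), and 2 were higher, RBL2 (0.26) and CCND3 (0.23), with the same counts adjusted over the list alone (camera adjusted p = 0.199). CCND3 and RBL2 were chosen for naming after their values were seen.

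Of the other fixed lists, the following did not pass camera in any comparison. In siATM against siNC the adjusted p was 0.0900 for other antioxidant genes, 0.199 for the CDK, cyclin and retinoblastoma family list, 0.445 for fatty acid synthesis, 0.520 for matrix proteases, 0.534 for mesenchymal genes, 0.570 for autophagy and lysosome, 0.600 for MYC and ribosome biogenesis, 0.619 for YAP and TAZ targets, 0.624 for heat shock and 0.905 for apoptosis regulators. In sip53 against siNC the same lists had adjusted p of 0.783, 0.820, 0.634, 0.634, 0.341, 0.634, 0.852, 0.879, 0.917 and 0.243.

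SESN3 and DEPP1, which are both known FOXO targets, rose after siATM (log2 fold changes 1.18 and 0.71), which led to the hypothesis that FOXO targets rose together. A list of 22 other known FOXO targets, 18 of them tested, was higher after siATM, with a median log2 fold change of 0.18, 7 members higher and 1 lower (camera p = 0.00124, and p = 0.0454 with an estimated correlation). Both p-values are unadjusted, unlike those of the fixed lists, and cannot be set beside them. The list was not tested after sip53. TXNIP (0.54), YPEL3 (0.51), TRIB1 (0.47), PIK3IP1 (0.67), FBXO32 (0.33), INSR (0.20) and KLF6 (0.21) rose, and MXI1 fell (−0.27). The result is consistent with higher FOXO activity after siATM but may also reflect slower growth, since the cell-cycle lists fell in the same arrays, and these were not separated by a test. The list and the idea come from the same data, so this remains a hypothesis.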
